A study of Mus musculus with 2 samples.

How the data were processed

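Chromatin accessibility was measured by DNase-seq in midbrain tissue of mouse embryos at embryonic day 11.5, in 1 group of 2 biological replicates, per the labels. Embryos of both sexes were pooled within each replicate, and the strain was B6NCrl. The replicate numbers are those of the labels, and the libraries were sequenced on different combinations of Illumina instruments. No control, input or second tissue was part of the series, so the only comparison between samples was replicate against replicate. With 1 group, a sequencing batch and a replicate cannot be told apart.

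The authors deposited a list of peaks and a list of hotspots for each replicate on the mouse build mm10, made from that replicate's own alignments and not from pooled reads, per the deposited file records. The aligner, the peak caller, their versions and their filters are not given in the sources used here. The signal value of each peak, as deposited, was a whole number from 1 to 150, with no stated normalization. It was treated as the authors' own value and used only to describe, rank or filter peaks within a list, or to compare the same peaks across both lists where that is said. The q-value of each deposited hotspot was on a −log10 scale, with a lowest value of 1.30 and a ceiling of 100. The score of each deposited hotspot was not used. Read depth is unknown, because the deposited lists give no read totals, and no counting interval or floor that needs depth is given.

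Peaks and hotspots on chromosomes 1 to 19 and X were used, and rows with the same coordinates were counted once. The reference was GRCm38.p6, which has the chromosome lengths of mm10, with GENCODE vM21 basic transcripts of protein-coding genes. No deposited peak extended past a chromosome end. A peak lay within 500 bp of 65.8% of annotated transcription start sites (TSSs) in replicate 1, against 10.5% after a 10 kb shift of the TSSs, and of 67.6% against 15.5% in replicate 2.

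Peaks of both replicates were merged where they overlapped by at least 1 bp. A merged region that held a peak of both replicates was called a consensus site, and the others are called sites of that replicate only. Random overlap was measured in 100 placements that rotated all peaks of a replicate along each chromosome, with a one-sided permutation p whose smallest possible value is 0.0099. The same placements were also scored within each decile of signal, a step chosen after seeing the data. Sites were classed by their midpoint as promoter (within 500 bp of a protein-coding TSS), exon, intron or intergenic. A gene had an accessible TSS where a peak of each replicate lay within 500 bp of any of its TSSs, whether or not these peaks overlapped. Distal sites lay more than 2.5 kb from every protein-coding TSS and were assigned to the nearest TSS within 100 kb.

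Gene lists were fixed before the data were examined. They held 372 genes in 19 lists, all found in the annotation and none in more than 1 list, and all olfactory receptor genes made the last of 20 lists. Each list was compared with 10000 random lists of the same size by a two-sided permutation test with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. The smallest unadjusted p that these lists can give is 0.0002. Random lists for accessible TSSs were matched on the decile of the observed to expected CpG ratio around the gene's 5′ end. Those for distal sites were matched on the decile of the gene's territory, the length of sequence nearest to its TSSs within the 100 kb limit. Genes are not replicates, so these p-values describe the 2 libraries and not a population of embryos. Random lists drew genes without regard to position, so genes that lie close together, such as Hox and olfactory receptor genes, counted as separate draws.

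Short consensus sequences of 19 transcription factor families or sites were searched on either strand in 150 bp around the midpoint of each distal consensus site. Each site had 1 control window 2 to 10 kb away, outside every peak and hotspot, with GC content within 2 percentage points. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 19 sequences. Of 60576 distal consensus sites, 3507 had no such window and were left out. Masked repeats made up 11.4% of site sequence and 29.0% of control sequence, so an alternative with windows matched on repeat content within 10 percentage points was added after seeing the data.

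Named genes followed a rule fixed before the data were examined. From each list it took the 2 genes with the highest mean percentile of TSS signal, the 2 with the most distal consensus sites and up to 2, in alphabetical order, with no TSS peak in either replicate. Genome-wide it took the 10 genes with the most distal consensus sites, the 10 strongest consensus sites and the 3 strongest peaks of each replicate without overlap in the other. Some genes that the rule takes are not reported here. Percentiles of TSS signal are among all protein-coding genes of that replicate.

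Alternatives fixed beforehand were the stronger 50% of peaks, equal numbers of peaks, each replicate alone with all of its peaks, a reciprocal overlap of 75 bp, hotspots in place of peaks, TSS windows of 1000 and 150 bp, a 50 kb limit on territories, random lists without matching, a window of 100 bp for sequences and a shift of each peak by 1 to 10 kb. Matching of territory and CpG ratio together, in 5 classes each, and the use of peaks written without a decimal point were added after seeing the data. The steps were tested on simulated data. All 30000 shared peaks placed in a list of 100000 were found. Among 21668 genes, 6.25% of 400 lists simulated without an excess of distal sites were called at an unadjusted p under 0.05, against 34.0% of 100 lists at 2-fold and 76.0% of 100 lists at 3-fold. All 600 sequences planted in 20000 windows were found. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.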

Results

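Accessible chromatin was mapped by DNase-seq, in which DNase I cuts open chromatin and the cut sites are sequenced, in mouse midbrain at embryonic day 11.5. At this stage the midbrain holds dividing neural progenitors and newly born neurons, with blood, vessel and mesenchymal cells as possible companions in dissected tissue. The group had 2 biological replicates, each a pool of male and female embryos. Replicate 1 had 306572 deposited peaks and replicate 2 had 455245, a mean of 380908 ± 105128 (SD, n = 2) and a ratio of 1.48. Nearly all peaks were 150 bp wide, and together they covered 44.1 Mb of chromosomes 1 to 19 and X in replicate 1 and 64.0 Mb in replicate 2. Hotspots, regions of elevated cutting with median widths of 214 and 201 bp, numbered 268062 and 376137. Every peak on these chromosomes overlapped a hotspot of its replicate by at least 1 bp. The median deposited signal was 18 in replicate 1 and 8 in replicate 2. Read depth is unknown for both libraries, so it is not known which of them measures weak sites with less error.

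The first question was how far the replicates marked the same sites. The strongest site shared by both lay at the promoter of Hjurp, which encodes a centromeric histone chaperone, at mm10 chromosome 1, positions 88277536 to 88277705, with signals of 148 and 130. Of the next 9 strongest shared sites, 7 were also promoters, those of Uba3, Cadm1, Hmgn2, Slc25a33, Cnot9, Rnft1 and Phlpp1. The others lay between genes 779 bp from a TSS of Ski, a regulator of TGF-β signalling, and in an intron 59442 bp from the nearest TSS, that of Gm42906. The 3 strongest peaks seen in replicate 1 only lay at the promoters of Cic, Fchsd2 and Dapk3, each with a signal of 142. Those of replicate 2 only lay in an exon near Brd2 and at the promoters of Pgrmc2 and Nsd2, with signals of 112, 108 and 104.

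Of replicate 1 peaks, 30.8% overlapped a peak of replicate 2, against 4.70% for randomly placed peaks (permutation p = 0.0099, the smallest possible). Of replicate 2 peaks, 21.7% overlapped a peak of replicate 1, against 3.35% at random (permutation p = 0.0099). With each peak moved by 1 to 10 kb instead, the random shares were higher, at 7.20% and 5.07%. Among the stronger 50% of peaks the observed shares were 52.9% and 37.3%. The share rose with the signal, from 3.38% in the lowest decile of replicate 1 to 86.4% in the highest, and from 2.28% to 81.3% in replicate 2. The lowest 2 deciles of replicate 1, at 3.38% and 3.91%, lay below all 100 random placements of their peaks, whose lowest values were 4.18% in both. The lowest 3 deciles of replicate 2, at 2.28%, 2.53% and 2.62%, likewise lay below their placements, with lowest values of 2.99%, 3.05% and 3.01%.

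**Figure D1:**
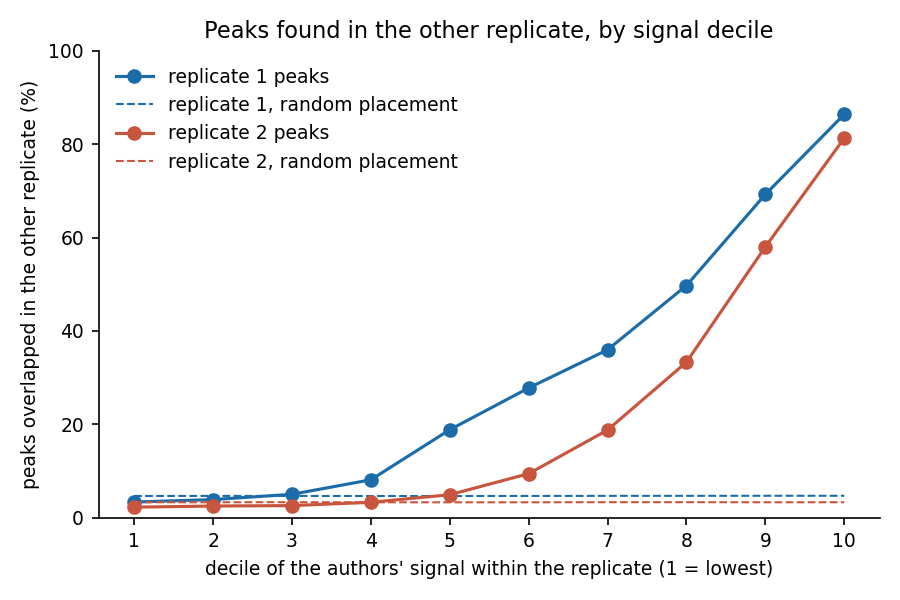
Share of peaks overlapped by a peak of the other replicate (vertical axis, percent) by decile of the authors' signal within the replicate (horizontal axis). Solid lines are the observed shares and dashed lines the means of 100 random placements; the shares reach 86.4% and 81.3% in the highest decile and lie near 2 to 5% in the lowest 3.

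Merging gave 583597 regions, of which 89717 (15.4%) were consensus sites, 191853 were in replicate 1 only and 302027 in replicate 2 only. Across 79741 pairs of peaks that matched 1 to 1, signals were correlated between replicates, with a Spearman's rho of 0.792 across peaks, which are not independent replicates. The median signal of these pairs was 52 in replicate 1 and 29 in replicate 2, and 88.4% of pairs had the lower value in replicate 2. Peaks without a partner had median signals of 10 and 6.

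Consensus sites lay at promoters more often than sites of a single replicate did, although 67.5% of consensus sites were distal. Promoters held 17047 consensus sites (19%), exons 4.67%, introns 35.5% and intergenic sequence 40.9%. Among sites of replicate 1 only the promoter share was 3.82%, and among those of replicate 2 only 2.47%. The odds ratio of a promoter position in consensus sites against sites of a single replicate was 7.60 (95% confidence interval 7.42 to 7.78, Fisher's exact test, two-sided), 3.73 with the stronger 50% of peaks and 16.3 with a promoter window of 150 bp. Within each replicate alone, promoters held 8.69% of the merged sites of replicate 1 and 6.30% of those of replicate 2.

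The second question was which genes had open promoters in the midbrain. The 26 neuronal differentiation genes all had an accessible TSS in both replicates, as did the 26 neural progenitor genes, the 24 housekeeping genes and the 20 cell cycle genes. Olfactory receptor genes, germline genes and liver genes were mostly closed, with accessible TSSs in 16 of 1134, 2 of 15 and 1 of 18. Posterior Hox genes, which pattern the trunk and tail, were open in 11 of 22. Genome-wide, 14190 of 21668 protein-coding genes (65.5%) had an accessible TSS and 6081 (28.1%) had no TSS peak in either replicate. The share was 68.7% ± 1.05 (SD, n = 2) per replicate. It rose with CpG content, from 6.05% in the lowest decile of the CpG ratio to 98.8% in the highest.

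Neuronal differentiation genes exceeded random lists matched on the CpG ratio around the gene's 5′ end, at 100% against 74.5% (permutation adjusted p = 0.001). A peak at any TSS of a gene counted, and the number of TSSs per gene was not matched. Tubb3, a neuronal tubulin, and Map2, a dendritic microtubule protein, led the neuronal differentiation list, with TSS signals at mean percentiles of 83.2 and 81.8. Neural progenitor genes were at 100% against 87.9% (permutation adjusted p = 0.05, just under the threshold before rounding), and this call ended with either replicate alone, with both other TSS windows and with hotspots. The list stayed at 100%, its highest possible share, in all of these except the 150 bp window, where it was at 88.5%. At 100% a missing call does not argue against an excess. Hes5, a Notch effector, and Pou3f2, a neural POU factor, led with percentiles of 92.8 and 92.7. Housekeeping genes, led by Ywhaz and Ppia, were at 100% against 87.9% and did not pass (permutation adjusted p = 0.0611). They too were at the highest possible share, so the missing call does not argue against an excess. With a 150 bp window they passed at 100% against 80.4% (permutation adjusted p = 0.004). Cell cycle genes were at 100% against 95.6% (permutation adjusted p = 0.87), led by the replication factors Mcm2 and Pcna. The central 95% of their random lists reached 100%, so a higher call was not possible for cell cycle genes.

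Posterior Hox genes were open less often than random lists matched on the CpG ratio around the gene's 5′ end, at 50% against 94.6% (permutation adjusted p = 0.001). These genes lie close together, with a median territory of 4.23 kb, and the p-value does not account for neighbours that share a state. Hoxb9 and Hoxc6 had no TSS peak in either replicate, whereas Hoxa10 and Hoxd10 had peaks with signals of 102 in replicate 1 and 72 and 55 in replicate 2. They were at 77.3% against 96.0% in replicate 2 alone (permutation adjusted p = 0.013) and with a 150 bp window at 27.3% against 86.2%. Without CpG matching this call ended (permutation adjusted p = 0.266). Germline genes were at 13.3% against 65.7% (permutation adjusted p = 0.001); Dazl, an RNA-binding protein of germ cells, had strong TSS peaks with signals of 123 and 76, while Ddx4 and Figla had none. Germline genes were at 6.67% with the stronger 50% of peaks and with a 150 bp window, and at 20% in replicate 2 alone. Olfactory receptor genes were at 1.41% against 11.5% (permutation adjusted p = 0.001), and at 8.73% against 17.1% in replicate 1 alone and 6.70% against 18.0% in replicate 2 alone. Liver genes were at 5.56% against 34.4% (permutation adjusted p = 0.016), with a TSS peak in both replicates at Trf, the transferrin gene, and none in either at Ahsg and Apoa1. In replicate 2 alone liver genes were at 27.8% and did not pass (permutation adjusted p = 0.544), and the call also ended with hotspots and with both other TSS windows.

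The regional neural lists had open promoters at rates near those of random lists. For midbrain and isthmus, midbrain neuron specification and hindbrain genes the central 95% of random lists reached 100%. These lists could therefore not be called higher at any share, and their tests could only give a lower call. Midbrain and isthmus patterning genes were open in 16 of 20, against 88.1% at random (permutation adjusted p = 0.473), and all 20 had a TSS peak in replicate 2. In replicate 2 alone, with a 1000 bp window, with hotspots and without CpG matching this list lay above random lists, without passing. Spry1, an inhibitor of FGF signalling, and En2, a transcription factor of the midbrain and cerebellum, had the highest signals, 114 and 94 for Spry1 and 111 and 82 for En2. Genes of midbrain neuron specification, led by Msx1 and Nkx6-1, were at 90.9% against 89.0% (permutation adjusted p = 1), but with a 150 bp window they were at 54.5%, below random lists at 80.6% (permutation adjusted p = 0.0227). Forebrain patterning genes, led by Lhx2 and Dlx6, were at 90.9% (permutation adjusted p = 0.781), and with a 150 bp window at 59.1% against 77.7%, below random lists without passing. Hindbrain and anterior Hox genes, with Egr2 among those of highest signal, were at 94.4% (permutation adjusted p = 0.651), and neurotransmitter genes, led by Slc17a6 and Gad1, at 73.3% (permutation adjusted p = 0.947).

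Markers of other cell types were intermediate, and none of these lists passed with CpG-matched random lists and a 500 bp window. Mesenchyme and neural crest genes were at 81.0%, with Tbx18 among the highest and no TSS peak at the collagen genes Col1a1 and Col3a1. Surface epithelium genes were at 66.7%, with no peak at the keratin genes Krt14 and Krt5. Glial genes were at 55.6%, with Pdgfra, a marker of oligodendrocyte precursors, at signals of 117 and 76 and no peak at Gfap. Endothelial genes were at 50%, led by Mfsd2a and Egfl7 and without a peak at Cdh5 and Emcn. Erythroid genes were at 47.1%, with 8 of 17 open in both replicates and 9 without a TSS peak in either. Tfrc led, and Sptb (signals of 51 and 60), Ank1 (61 and 53) and Nfe2 (48 and 28) also had TSS peaks in both. The red-cell genes Alas2 and Gata1 had no peak, and both lie on chromosome X, where peaks were sparse. Heart and skeletal muscle genes were at 35%, with no peak at Myf5 and Myf6, and microglia and macrophage genes at 16.7%, with no peak at Aif1 and C1qb. The permutation adjusted p of these 7 lists ranged from 0.198 to 0.87. Endothelial genes were called lower with a 150 bp window, at 33.3% against 59.8% (permutation adjusted p = 0.0309), and microglia and heart and muscle genes without CpG matching (permutation adjusted p = 0.000571 and 0.0212). Heart and muscle genes were at 65% in replicate 2 alone, above random lists at 58.9% without passing, and microglia and macrophage genes were at 27.8% against 34.98% (permutation adjusted p = 0.944).

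**Figure D2:**
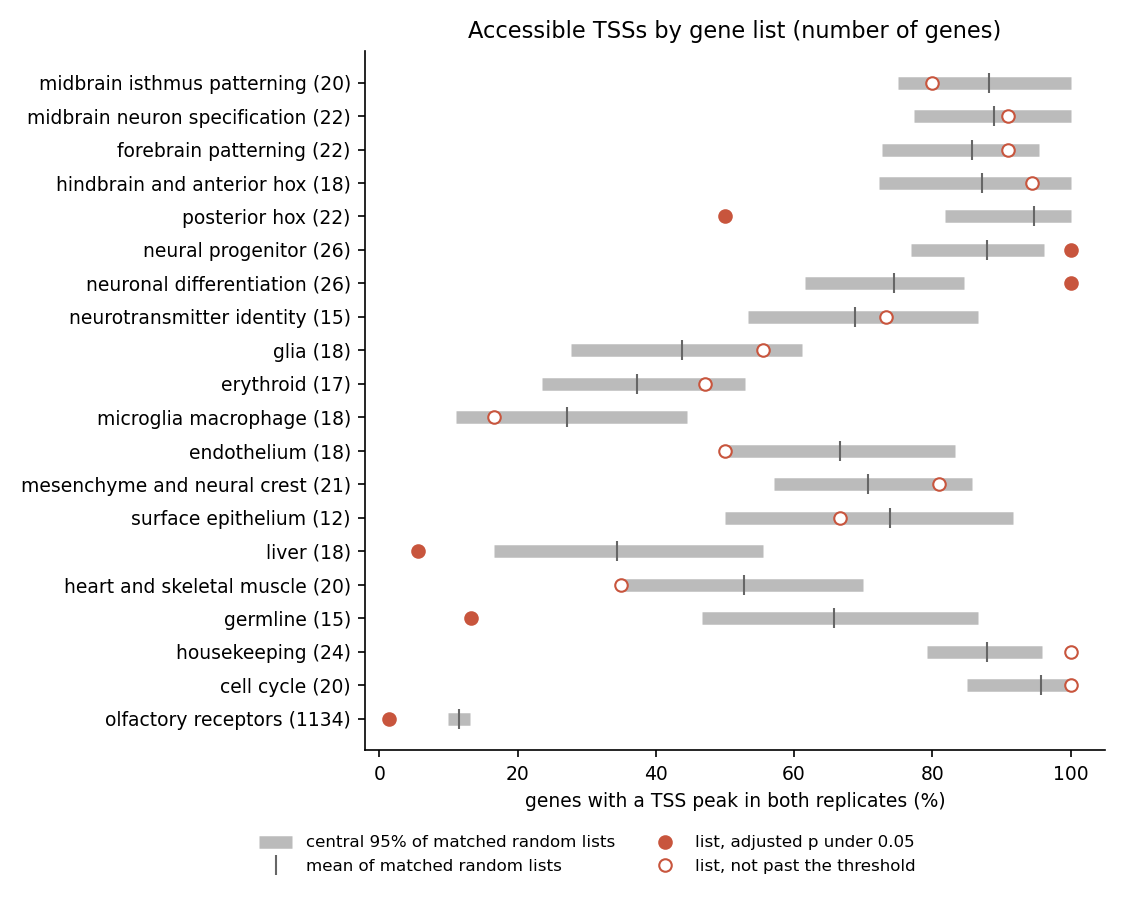
Share of genes with a TSS peak in both replicates (horizontal axis, percent) for 20 gene lists, with the number of genes in brackets. Circles are the lists, filled where the adjusted p was under 0.05; grey bars span the central 95% of 10000 random lists matched on CpG ratio and ticks their mean, and posterior Hox genes, at 50%, lie below a matched mean of 94.6%.

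The third question was which genes were surrounded by distal accessible sites. Midbrain and isthmus patterning genes had 14.7 distal consensus sites per gene against 3.53 for random genes with territories of like size, and neural progenitor genes had 14.4 against 3.17. Pax2, a transcription factor of the midbrain-hindbrain boundary, had 42 and Lmx1b, which acts in isthmus and dopamine neuron development, had 31. Sox2, a transcription factor of neural stem cells, had 43 and Pou3f3 had 39. Olfactory receptor genes had 0.160 per gene against 0.760. Across all 21668 genes the mean was 2.06 and the median 1, and 9369 genes had none.

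The excess relative to random genes was smaller in single replicates, at 25.95 against 11.6 in replicate 1 and 58.75 against 18.4 in replicate 2 for midbrain and isthmus genes, and 25.7 against 10.7 and 42.5 against 16.7 for neural progenitor genes. Olfactory receptor genes had 1.14 against 1.89 in replicate 1 alone.

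In all, 7 lists were above random lists and 1 below. Midbrain and isthmus patterning, neural progenitor, neuronal differentiation (9.38 against 3.38 per gene), forebrain patterning (8.95 against 2.97) and midbrain neuron specification (8.82 against 3.65) each had a permutation adjusted p of 0.000667, from the smallest p that the random lists can give. Ebf3, a transcription factor of neuronal differentiation, had 23 distal consensus sites. Nkx6-1 and Sox14, both transcription factors of ventral and inhibitory neuron lineages, had 28 each. In the forebrain list Dlx2 had 21 and Lhx2 had 17.

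Hindbrain and anterior Hox genes had 5.39 per gene against 1.70 (permutation adjusted p = 0.00114), with 22 at Lbx1 and 14 at Atoh1. In replicate 2 alone this list was at 13.2 against 8.50 and did not pass (permutation adjusted p = 0.267). Glial genes had 5.33 against 2.66 (permutation adjusted p = 0.0435), with 14 at Mbp and 9 at Mobp, both myelin genes. The glial call ended in each replicate alone, at 10.7 against 8.73 in replicate 1 and 18.4 against 13.7 in replicate 2.

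The remaining lists did not pass, among them neurotransmitter, cell cycle and housekeeping genes as well as lists of other tissues. Mesenchyme and neural crest genes had 5.10 per gene, with 16 at Tfap2b, heart and skeletal muscle genes 4.75, with 30 at Hand2, a transcription factor of heart and sympathetic neurons, and endothelial genes 4.72, with 17 at Kdr. Neurotransmitter genes had 3.67, with 8 at Gad1 and at Slc18a2, and microglia and macrophage genes 2.61, with 9 at Irf8 and at Runx1. Cell cycle genes had 2.05, housekeeping genes 2.04, surface epithelium genes 2.00, liver genes 1.22, erythroid genes 1.18, posterior Hox genes 1.05 and germline genes 1.00. The lowest permutation adjusted p among these was 0.0915, for heart and skeletal muscle. That list passed with replicate 2 alone, with a 50 kb limit and without territory matching, and with territory and CpG matching, an alternative chosen after seeing the data. Posterior Hox genes (9.77 against 2.51, permutation adjusted p = 0.002) and cell cycle genes (14.6 against 6.53, permutation adjusted p = 0.0135) also passed in replicate 2 alone. Sites of replicate 2 only were uneven in both lists, with 61 at Hoxb13 and 69 at Mki67 against 0 at Hoxc6 and Mcm2. Without territory matching endothelial genes (permutation adjusted p = 0.0265) and mesenchyme and neural crest genes (permutation adjusted p = 0.0095) passed.

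**Figure D3:**
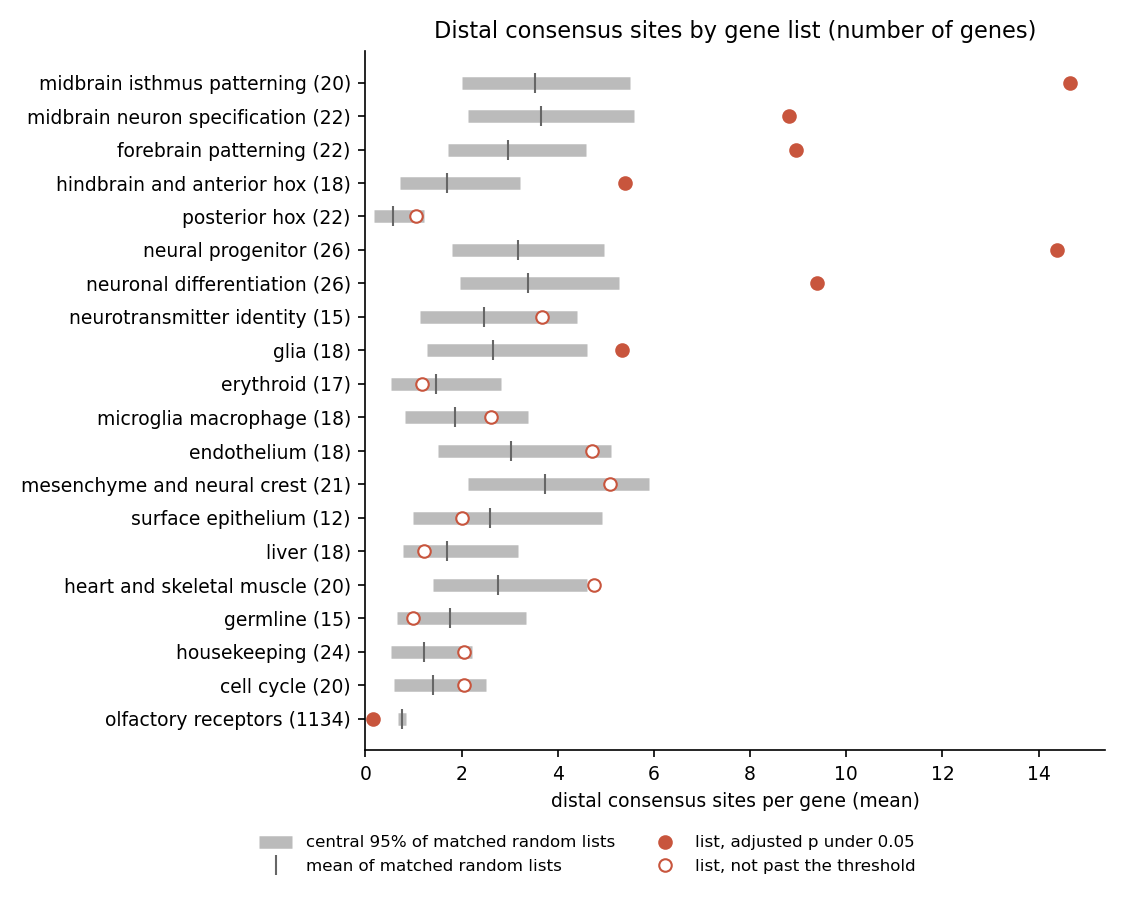
Mean number of distal consensus sites per gene (horizontal axis) for 20 gene lists, with the number of genes in brackets. Circles are the lists, filled where the adjusted p was under 0.05; grey bars span the central 95% of 10000 random lists matched on territory and ticks their mean, and midbrain and isthmus patterning (14.7) and neural progenitor genes (14.4) lie above matched means of 3.53 and 3.17.

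Genome-wide, Hs3st3b1, which encodes a heparan sulfate sulfotransferase, had the most distal consensus sites, 65, followed by Bcor, a corepressor gene on chromosome X, with 61. Pde4d and Sox2 had 43 each, Pax2 had 42, Pou3f3 had 39, Auts2 and Bach2 had 38 each, Pax6 had 37 and Uncx had 36. Of these 10 genes, Sox2, Pax2, Pou3f3 and Pax6 belonged to the lists fixed beforehand. Their counts were not scaled for territory. It was 1225.9 kb for Pde4d, 698.8 kb for Auts2 and 361.1 kb for Bach2, against 195 kb for Sox2 and 118.9 kb for Uncx. Pax2 lies on chromosome 19 at positions 44756045 to 44837871 of mm10, on the plus strand. From 100 kb before to 100 kb after the gene there were 60 consensus sites of any class, 42 sites of replicate 1 only and 79 of replicate 2 only.

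**Figure D4:**
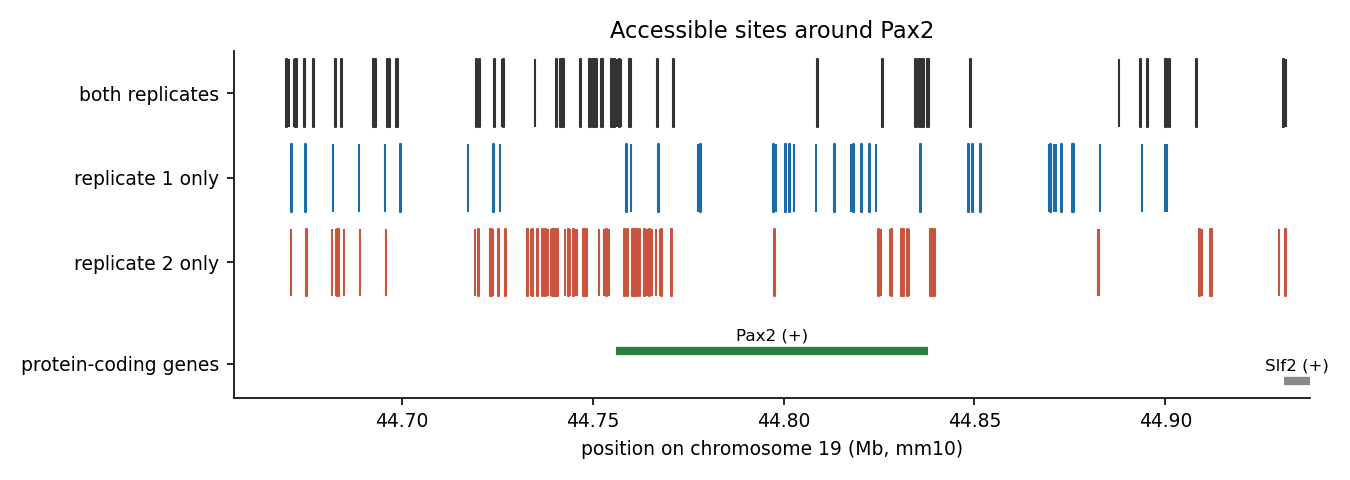
Map of accessible sites around Pax2 on chromosome 19 (horizontal axis, position in Mb, mm10). Each bar is a merged site, in rows for the 60 sites of both replicates, the 42 of replicate 1 only and the 79 of replicate 2 only; horizontal bars at the bottom are protein-coding genes with their strand.

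Distal consensus sites were rich in the sequence of CTCF, the insulator protein that anchors chromatin loops, and of several families of transcription factors. With no second tissue in the series, a neural character of these sequences was not tested. The CTCF sequence was in 8.83% of 57069 distal sites and in 0.0824% of control windows, an odds ratio of 118 (95% confidence interval 88.2 to 157), and with control windows matched on repeats it was in 4875 sites against 21 windows, with an interval of 166 to 392 for the odds ratio. The RFX half-site was in 604 sites against 33 control windows (odds ratio 18.5, Fisher's exact test, adjusted p = 7.16e-137), and the full RFX palindrome in 52 sites and 0 control windows, at least 17.3-fold higher against a floor of 3 windows. The octamer of POU factors was in 2.46% against 0.958% (odds ratio 2.60, Fisher's exact test, adjusted p = 5e-87) and the SOX sequence in 9.31% against 4.95% (odds ratio 1.97, adjusted p = 1.79e-181). The homeodomain sequence TAATTA (odds ratio 1.80, Fisher's exact test, adjusted p = 1.25e-58) and the OTX sequence (odds ratio 1.47, adjusted p = 6.68e-13) were also higher. Of the E-box sequences bound by bHLH factors, CAGCTG was in 14.4% against 9.08% (odds ratio 1.68) and CAGATG in 15.3% against 12.9% (odds ratio 1.23). Over all distal sites of replicate 2 the odds ratios were 39.4 for CTCF, 3.58 for the RFX half-site, 1.16 for SOX, 1.13 for the octamer and 1.12 for TAATTA, all still called.

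In Fisher's exact tests 14 of the 19 sequences were higher in distal sites and 1 was lower. The lower one was the GATA sequence, in 1.36% against 1.64% (odds ratio 0.830, Fisher's exact test, adjusted p = 0.000227). Over all distal sites of replicate 2, consensus sites included, the GATA odds ratio was 1.04. The sequences of NFI (odds ratio 9.34, and 4.17 with repeats matched), NRF1 (3.30), MEF2 (2.08), ETS (1.35, Fisher's exact test, adjusted p = 0.0313) and LEF/TCF (1.16, adjusted p = 0.0278) were higher. NFI was at 1.85, NRF1 at 1.61 and MEF2 at 1.25 over all distal sites of replicate 2. The ETS call ended with replicate 2 alone (1.14) and with control windows matched on repeats (1.08), and the LEF/TCF call with the stronger 50% of peaks (1.12) and with replicate 1 alone (1.02). AP1 (odds ratio 1.04), HNF1 (3 sites against 1 window), HNF4 (1.05) and the p53 half-site (1.00) did not pass. With repeats matched AP1 (0.923, Fisher's exact test, adjusted p = 0.0356) and the p53 half-site (0.861, adjusted p = 0.00735) were lower. A match is a sequence match and does not show binding.

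Peaks were sparse on chromosome X. It held 30.4 peaks per Mb in replicate 1 and 39.3 in replicate 2, against 122 and 182 on the autosomes, a ratio of 0.233 ± 0.0231 (SD, n = 2). Chromosome 11 was densest, with 141 and 224 peaks per Mb. An accessible TSS was present at 49.6% of the 948 X-linked genes and 66.2% of autosomal genes. Given the CpG ratios of the X-linked genes, 57.5% would be open at autosomal rates.

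**Figure D5:**
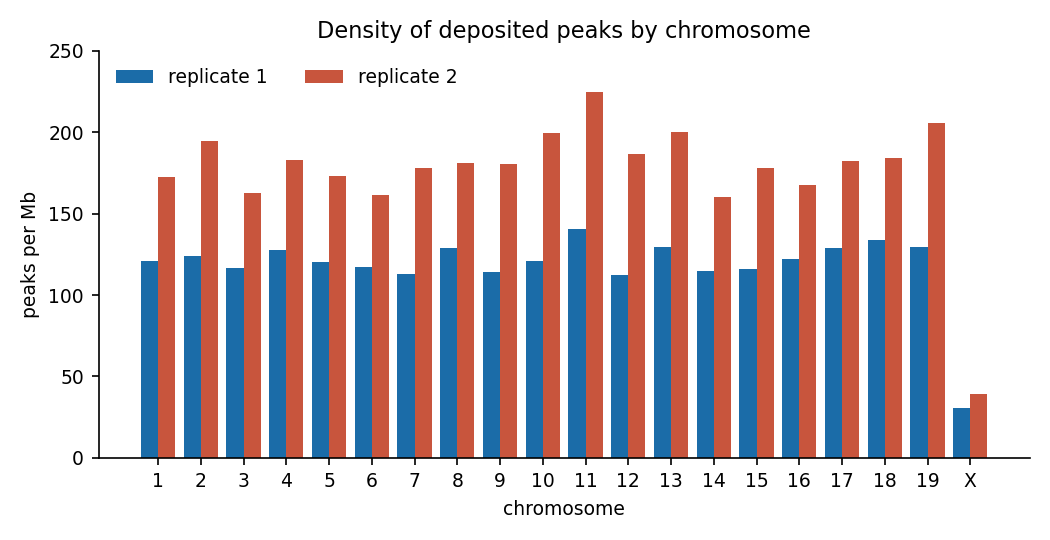
Deposited peaks per Mb (vertical axis) on chromosomes 1 to 19 and X (horizontal axis), with a bar for each replicate. Chromosome X has 30.4 and 39.3 peaks per Mb, below every autosome in both replicates.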

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

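The tests on the mitochondrial gap, on chromosome X and on the unequal peak numbers were chosen after those patterns had been seen and before their own results were known, except that the comparison of both replicates around non-neural genes was added after the value of replicate 2 was known.

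Peaks outside the comparisons were present in every class of sequence left out. Chromosome Y held 151 peaks in replicate 1 and 184 in replicate 2, in pools that included male embryos. Unplaced and unlocalised sequences held 533 and 516. The mitochondrial genome held 19 and 31, with median signals of 149 and 93. All 9 peaks of replicate 1 with a signal of 150, the highest value in either list and equal to the width of a peak in bp, were mitochondrial.

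Both replicates left the same stretch of the 16299 bp mitochondrial genome without a peak, from position 6366 to 11095 (4730 bp), while the next longest gaps were 1450 and 730 bp. A candidate explanation is that reads which also match a nuclear copy were removed before peaks were called. Of the 32-base words that start in the stretch, 97.1% occur exactly on a nuclear chromosome, against 17.8% elsewhere in the mitochondrial genome. All 4563 of these shared words occur in mm10 chromosome 1, positions 24611535 to 24616184. The test is in line with such a filter, which the sources used here do not state, and no biological explanation was tested.

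Chromosome X had 0.233 times the autosomal density of peaks. The tables argue against repeats as the whole cause, since the ratio per Mb of unmasked sequence was 0.296 ± 0.0294 (SD, n = 2), and against low gene number, since the ratio per TSS was 0.394 ± 0.0392. The lower copy number of X in a pool that includes males stays open: the share of genes with an accessible TSS was 0.737 times the autosomal share, less reduced than peak density but below 1. Part of this reduction goes with CpG content. At autosomal rates for their CpG ratios, 57.5% of X-linked genes would be open in both replicates. The observed share was 49.6%, against 66.2% of autosomal genes. Signals at accessible X-linked TSSs had medians 0.794 and 0.606 times the autosomal ones. Low copy number and low accessibility of X cannot be told apart, because the series has no input and male and female embryos were pooled in both replicates.

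Replicate 2 had more peaks with lower signals. Deeper sequencing as the only difference is argued against, unless the signal was scaled for depth, because the median log2 ratio of replicate 2 to replicate 1 at shared peaks was -0.74. Depth together with a smaller share of reads in peaks stays open, because neither is known for these libraries. GC content is argued against only as the whole cause: median GC of sites of replicate 2 only differed from that of replicate 1 only by -0.667 percentage points, but the ratio of their numbers was 1.43 below 35% GC, 1.57 to 1.70 in the bins from 35 to 55%, 1.34 at 55 to 60% and 1.01 at 60% or more, so a part that depends on GC stays open. Cells of non-neural types stay open: genes of 7 non-neural lists had 13.6 distal sites of replicate 2 only per gene against 10.1 in matched random lists (permutation p = 0.0142), which passed the test planned for it, but 6.64 of replicate 1 only against 5.43 (permutation p = 0.122), and the difference between replicates did not pass (permutation p = 0.514). Whether such cells could account for part of the excess cannot be told apart from other causes, and midbrain and isthmus genes had a larger excess, 43.8 against 14.8.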

How the results depend on the processing

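The matching of territory and CpG together, of repeats in control windows and the use of peaks without a decimal point were chosen after seeing the data, and the other alternatives were fixed beforehand. Of 538 values across 73 results and 17 settings, 454 kept their direction and their side of the threshold or their range. No pairing of samples arises, and no paired analysis was possible because there is 1 group. Overlap between replicates exceeded random placement in every setting run. With the stronger 50% of peaks the mean number was 190056, the rank correlation 0.742 and the X ratio 0.280. The correlation was 0.777 with equal numbers of peaks and 0.803 with a 75 bp overlap. Without a replicate, promoter shares ranged from 6.30 to 8.69% and accessible TSSs from 68.0 to 69.5%; windows of 1000 and 150 bp gave 67.2 and 59.1%. At the TSS, 1 list was higher without either replicate, with the 1000 bp window and with hotspots, and 7 without CpG matching. Neural progenitor genes stayed at 100%, their highest possible share, but lost their call without either replicate, with the 1000 bp window and with hotspots. They fell to 88.5% at 150 bp. Liver genes lost it without replicate 1 (27.8%), at 1000 bp (16.7%), at 150 bp (5.56%) and with hotspots (11.1%), and posterior Hox genes (50%) without CpG matching. Midbrain neuron specification genes were below random lists, and called, at 150 bp (54.5%). Housekeeping genes gained a call as higher and endothelial genes as lower at 150 bp. Without CpG matching midbrain neuron specification, forebrain, hindbrain, housekeeping and cell cycle genes gained one as higher and microglia and heart and muscle genes as lower. Lists without a call turned direction: midbrain and isthmus genes without replicate 1 (range 80 to 100%), at 1000 bp (95%), with hotspots (90%) and without CpG matching (80%); forebrain (59.1%), hindbrain (77.8%), neurotransmitter (53.3%) and mesenchyme genes (61.9%) at 150 bp; glial (55.6%), erythroid (47.1%) and epithelium genes (66.7%) without CpG matching; and heart and muscle genes without replicate 1 (45 to 65%). Distal calls were lost for hindbrain genes without replicate 1 (13.2 sites per gene, 16.0 without replicate 2) and for glial genes without either replicate (10.7 to 18.4). They were gained by posterior Hox and cell cycle genes without replicate 1, by heart and muscle genes in 4 settings and by endothelial and mesenchyme genes without territory matching. Without a replicate, lists without a call turned direction at neurotransmitter (9.87 to 12.1), erythroid (4.76 to 12.4), mesenchyme (12.5 to 27.4), epithelium (10.2 to 16.7) and germline genes (6.07 to 8.40 sites), as did posterior Hox (1.05), housekeeping (2.04) and cell cycle genes (2.05) without territory matching. Without a replicate, odds ratios ranged from 0.927 to 1.04 for GATA, turned without replicate 1 and leaving 0 lower sequences, from 1.14 to 1.40 for ETS, lost without replicate 1, and from 1.02 to 1.16 for LEF/TCF; LEF/TCF was not called without replicate 2 or with the stronger 50% (1.12). With repeats matched, 3 sequences were lower, AP1 (0.923) and p53 (0.861) having reversed, and ETS (1.08) was not called. The p53 value also turned with the stronger 50% (0.911) and a 100 bp window (0.932), and HNF4 without replicate 2 (0.973 to 1.16); AP1 was called higher without either replicate, HNF4 without replicate 1 and p53 without replicate 2. The cause was not tested for any of these. Unknown read depth limits all statements on weak peaks.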

Other observations

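The tests on gene families were chosen before their results were known and after the lists had been seen, and those on sites of a single replicate, the CpG matching of families and the families without listed genes were chosen after seeing the data.

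Several families of developmental transcription factors, among them Pax, Sox, Zic and Irx, had more distal consensus sites than random genes with territories of like size. Among 25 families defined by gene symbol, 10 were above territory-matched random lists and 5 below in permutation tests with Benjamini-Hochberg adjustment. Pax genes had 19.2 distal consensus sites per gene against 4.22 at random, Irx genes 14.2 against 5.31, Zic genes 14.0 against 2.63 and Sox genes 13.7 against 3.52. Lhx (9.25), Pou (8.75), Nkx (8), Fox (6.27), Wnt (6.11) and Hox genes (1.56 against 0.610) were also above their random lists, the Hox value being below the mean of 2.06 over all genes. Fgf genes had 2.55 against 2.98 and Bmp genes 3 against 3.30 and did not pass; no difference between families was tested. Potassium channel genes (Kcn, 3.36 against 3.23), solute carriers (Slc, 2.36 against 2.28) and zinc finger genes (Zfp, 2.01 against 1.85) did not pass. Vomeronasal receptors (Vmn, 0.263 against 1.97), bitter taste receptors (Tas2r, 0.400), beta-defensins (Defb, 0.429), serpins (0.738) and cytochrome P450 genes (Cyp, 1.08) were below. Of these 15 calls, 13 passed with CpG content matched as well; beta-defensins (permutation adjusted p = 0.351) and bitter taste receptors (permutation adjusted p = 0.0711) did not. The hypothesis that developmental regulators carry more distal sites than genes of like territory was met by 10 of the 12 families named for it, but 73 of their 213 genes, among them Sox2, Pax2, Pou3f3 and Nkx6-1, belonged to the lists already seen. Without the listed genes, 6 of the 11 families that kept at least 3 genes passed (Sox, Fox, Irx, Lhx, Nkx and Wnt), while Pax (7.33 against 3.46, 3 genes), Hox (2.20 against 0.844, 5 genes) and Pou (4.69 against 3.33) did not, nor did Fgf and Bmp. Zic kept too few genes to be tested. The tests are in line with the hypothesis for those 6 families and leave it open for the others.

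The replicates differed in where their own sites lay. Distal sites of replicate 2 only numbered 43.8 per midbrain and isthmus gene and 8.73 per posterior Hox gene, against 11.1 and 0.545 of replicate 1 only. Those at posterior Hox genes were uneven, with 61 of replicate 2 only at Hoxb13 and 26 at Hoxb9. Hoxa10 had 4, Hoxd10 had 6 and Hoxc6 had 0. Relative to each replicate's mean over all genes, midbrain and isthmus genes were at 5.34 times in replicate 2 and 2.57 times in replicate 1. For both lists the difference in these multiples exceeded that of territory-matched random lists (permutation adjusted p = 0.002 and 0.00267). Cell cycle genes moved the same way, at 1.52 against 0.535 times the mean (permutation adjusted p = 0.036). Their sites of replicate 2 only were uneven as well, with 69 at Mki67 and 58 at Ccnd2 but 0 at Mcm2 and Pcna. A shift shared by the list is therefore not shown. Hindbrain and anterior Hox genes were at 0.928 in replicate 2 and 2.40 in replicate 1 (permutation adjusted p = 0.036), and surface epithelium genes at 0.996 and 3.37 (permutation adjusted p = 0.042). Olfactory receptor genes were at 0.0700 and 0.227 (permutation adjusted p = 0.002). The 14 other lists did not pass. Whether both libraries were dissected and digested alike is not given in the sources used here, so a difference in dissection or digestion stays open for these shifts and was not tested.

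Peaks written with a decimal point, 13.9% of replicate 1 and 22.7% of replicate 2, had a median signal of 6 in both, against 21 and 8 for the others. On average 41.3% of them were alone in their hotspot and 55.1% overlapped another peak of their replicate. Of the peaks written without one, 7.86% and 15.7% overlapped another peak of their replicate.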
